A study of Mus musculus with 2 samples.

How the data were processed

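Ribosome-associated RNA was measured by RNA sequencing in 2 libraries of 1 group, the dentate gyrus of adult mice of the Lypd1-TRAP line OI82. In such a line, translating ribosome affinity purification (TRAP) uses a ribosomal protein, Rpl10a, fused to EGFP and expressed under the regulatory sequence of the gene the line is named for. Per the labels' protocols, the dissected dentate gyrus was homogenised, tagged polysomes were pulled down with anti-EGFP antibodies on magnetic beads, and RNA was purified from the pull-down. Both libraries are pull-downs. An input library, an untagged control or a second cell type was not analysed here, so all values are levels within the purified RNA and none is an enrichment over the tissue. The labels do not say whether the replicates came from separate animals or pools of animals, so the spread between them may be partly technical.

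The deposited values are counts per gene symbol, not normalised. Per the submitters' processing notes, STAR 2.0.0e, HTSeq and genome build mm10 were named. The annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart. HTSeq's summary lines and a line named unknown, which held 0 counts, name no gene and were kept out of the library totals. Over all lines, 65.0% of counts in replicate 1 and 64.9% in replicate 2 were on gene lines. Genes with near-identical copies, such as haemoglobin and ribosomal protein genes, can lose reads to the class of non-unique alignments. No symbol in the tables begins with mt-, so mitochondrially encoded transcripts have no line of their own. Lars2 and the ribosomal RNA gene Rn45s were kept in the totals, and an alternative left both out.

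Levels are counts per 1000000 counts on gene lines (CPM), computed here, and are given as mean ± SD over the 2 libraries. CPM is not corrected for transcript length, so levels of different genes compare read counts and not molecules. A gene counted as detected at a CPM of at least 1 in both libraries. A count of 0 allows up to 3 counts, which is a CPM of 0.0958 in replicate 1 and 0.0917 in replicate 2. Intervals and floors cover counting error only, since the reads carry no molecular identifiers and are not independent molecules.

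The design has no second group, so no test between conditions was possible and no p-value is given. The 2 libraries were compared with each other by Pearson and Spearman correlations across genes of log2(CPM + 1), by the ratio of the chi-square statistic of their counts to its degrees of freedom, and by the biological coefficient of variation from edgeR 4.0.16 in an intercept-only fit. Log2 ratios of replicate 2 to replicate 1 used TMM-scaled totals and a prior count of 2. Their 95% intervals are exact (Clopper-Pearson) intervals of the share of counts. They compare these libraries and not conditions.

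Gene lists were written before the data were examined. They comprise 22 lists of cell type markers and 19 lists of receptors, channels, peptides and other gene groups. Ccn3 and Nectin3 were found under their older symbols Nov and Pvrl3 and 2 haemoglobin members were not found. A list's level is the median CPM of its members, with the percentile of that median among 10000 random lists of the same size drawn from genes with a count in both libraries. A list's difference between the libraries is the median log2 ratio of its members with a mean CPM of at least 1, with its percentile among 10000 random lists matched on mean expression in 20 bins. Random members were drawn with replacement. Genes are not replicates, so these percentiles describe the libraries and are not p-values. Lists of delayed and rapid activity genes and of clock output genes were added after a first look at the list members and at the genes that differed most. Which lists are followed through every setting in detail was also chosen after that look. On simulated libraries made from the real means and totals with a common coefficient of variation, 98.5% of 200 genes changed 4-fold came out past 2-fold in the right direction for replicate 2 against replicate 1. In the same simulation 5.52% of unchanged genes passed 2-fold, and 9 of 200 lists of 15 unchanged genes fell outside the central 95% of random lists. Its coefficient of variation was estimated from these same 2 libraries. Its genes varied independently, which members of a real list need not do.

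Named genes follow a rule set in advance. They are the 10 most abundant nuclear-encoded genes, the 3 most abundant mitochondrially encoded ones, of which the tables hold none, the up to 4 most abundant members of each list, any member of the receptor, channel, peptide and transmitter lists, list members below a CPM of 1, the 10 genes with the largest log2 ratio in each direction at a mean CPM of at least 10, Lypd1 and Rpl10a, and the sex-linked transcripts. Fosb, Egr1, Npas4, Dusp1, Fos, Aqp4, Gfap, Lhx6, Dlx1, Bhlhe41 and Lars2 lie outside this rule and were named after their values were seen. Symbols were matched to GENCODE M21 on GRCm38, which is the assembly mm10, for positions and exon lengths. Of the symbols with a count, 87.2% matched, 99.6% of list members had an exon length, and coordinates are 1-based. Alternatives were the detection threshold, the pseudocount, DESeq2 1.42.0 size factors and dispersions, library totals alone, length-scaled levels, other backgrounds and expression bins, and each library alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.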

Results

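Ribosome-bound RNA from the dentate gyrus of adult Lypd1-TRAP mice was counted in 2 libraries, both immunopurified. Replicate 1 held 31309643 counts on genes and replicate 2 held 32711412. Of the 32531 gene symbols in the tables, 16707 had a count in both libraries and 12402 reached a CPM of at least 1 in both. The question is what the neurons of the dentate gyrus that this line marks translate. With 1 group, the comparisons are between gene groups within the purified RNA and between the 2 libraries.

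The most abundant messages included genes of neuronal signalling and synaptic release, a grouping that was not tested. The highest line was the ribosomal RNA gene Rn45s (56081 ± 9926 CPM, SD, n = 2), followed by the nuclear long noncoding RNA Malat1 (14106 ± 5597 CPM). The next gene was Snap25, a component of the vesicle fusion machinery, at 12444 ± 200.1 CPM. Other genes among the 10 most abundant were the kinase subunit Camk2a (6160 ± 419 CPM), Calm2 (4937 ± 687 CPM), the 14-3-3 genes Ywhaz (6213 ± 930 CPM) and Ywhae (4513 ± 162 CPM), the microtubule protein gene Map1b (4639 ± 484 CPM) and the calcineurin subunit Ppp3ca (4311 ± 609 CPM). The 10 most abundant genes took 12.1% of counts in replicate 1 and 11.9% in replicate 2. Rn45s alone took 6.31% and 4.91%, and its counts do not separate precursor from mature ribosomal RNA. All 18 synaptic vesicle genes and all 12 pan-neuronal genes were detected, with list medians of 454 and 609 CPM, both at percentile 100 of random lists.

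Lypd1, the gene the line is named for, is a protein-coding gene on chromosome 1 (125867622 to 125913101, minus strand, GRCm38). It was counted at 229 ± 49.9 CPM and ranked 822 of all genes. Rpl10a, on chromosome 17 (28328471 to 28331033, plus strand), stood at 229 ± 42.1 CPM and ranked 5 among 83 cytosolic ribosomal protein genes, whose median was 77.4 CPM. Reads from the tagged transgene and from the endogenous Rpl10a gene cannot be told apart in these counts.

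Markers of dentate granule cells, the principal neurons of the region, stood far above those of every other cell class in both libraries. All 12 were detected, with a median of 180 ± 12.4 CPM and a percentile of 100 among random lists in each library. Prox1, the transcription factor that specifies granule cell identity, was at 1146 ± 65.5 CPM. Sema5a (890 ± 49.8 CPM), Stxbp6 (806 ± 10.6 CPM) and the calcium-binding protein gene Calb1 (323 ± 60.7 CPM) came next. The list with the second highest median, that of CA2 pyramidal cells, was at 13.4 CPM.

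Hilar mossy cell markers were near the detection threshold of 1 CPM, with a median of 1.04 CPM and 3 of 7 members detected. None had 0 counts in both libraries. Calb2, the calretinin gene, was at 2.49 ± 1.49 CPM and the dopamine receptor gene Drd2 at 0.296 ± 0.0571 CPM, while Ajap1 was the highest member, at 41.4 ± 13.3 CPM. The counts of Prox1 were 310 times those of Calb2 in replicate 1 and 830 times in replicate 2. Markers of the CA fields had medians of 13.4 CPM for CA2, 8.49 CPM for CA1 and 6.72 CPM for CA3, with Cpne4 (205 ± 2.34 CPM) and the CA1 marker Wfs1 (66.7 ± 9.58 CPM) the highest members. Markers of neural progenitors and newborn neurons had a median of 2.85 CPM. Dcx, a marker of immature neurons, was at 9.62 ± 1.20 CPM, and Eomes and Igfbpl1 had 0 counts. Sox11 was the exception in that list at 187 ± 176 CPM, with 63.3 CPM in replicate 1 and 312 CPM in replicate 2.

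GABAergic markers were uneven. The enzymes of GABA synthesis, Gad1 (62.8 ± 18.1 CPM) and Gad2 (31.3 ± 16.4 CPM), were well detected, while the vesicular GABA transporter Slc32a1, which loads GABA into vesicles, was at 0.535 ± 0.237 CPM. The median of the 10 pan-GABAergic markers was 1.68 CPM. Interneuron class genes were scarce, with Pvalb at 0.201 ± 0.148 CPM, Sst at 2.67 ± 0.701 CPM and Vip at 0.156 ± 0.00484 CPM. Higher members of these lists included Kcnc1 (112 ± 17.9 CPM), Cck (108 ± 48.2 CPM) and Adarb2 (103 ± 9.12 CPM). Of the Cajal-Retzius cell markers, Reln (39.0 ± 14.8 CPM) was the highest, with a list median of 9.27 CPM.

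Most lists of non-neuronal markers were low. Microglial markers had a median of 0.584 CPM, with C1qa and C1qb at 0 counts in both libraries. Medians were 1.94 CPM for endothelial cells, 1.04 CPM for pericytes and smooth muscle cells, 2.22 CPM for oligodendrocyte precursors, 0.427 CPM for meningeal fibroblasts, 0.915 CPM for red blood cells, 0.0465 CPM for choroid plexus and 0.0306 CPM for ependymal cells. The thalamic list, for tissue below the dentate gyrus, had a median of 2.84 CPM. Oligodendrocyte and astrocyte markers were higher, at 6.34 and 9.54 CPM. Their percentiles among random lists were 29.5 and 47.4, with 8 of 10 and 10 of 11 members detected. Mbp, which encodes a myelin protein, was at 113 ± 19.0 CPM, and the glutamate transporter Slc1a2 at 401 ± 16.3 CPM, against 9.54 ± 3.46 CPM for the astrocyte filament gene Gfap and 15.5 ± 1.74 CPM for the water channel Aqp4. In CPM per kilobase of exon, the granule cell list kept its place at percentile 99.95 and the microglial list was at percentile 0.

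**Figure D1:**
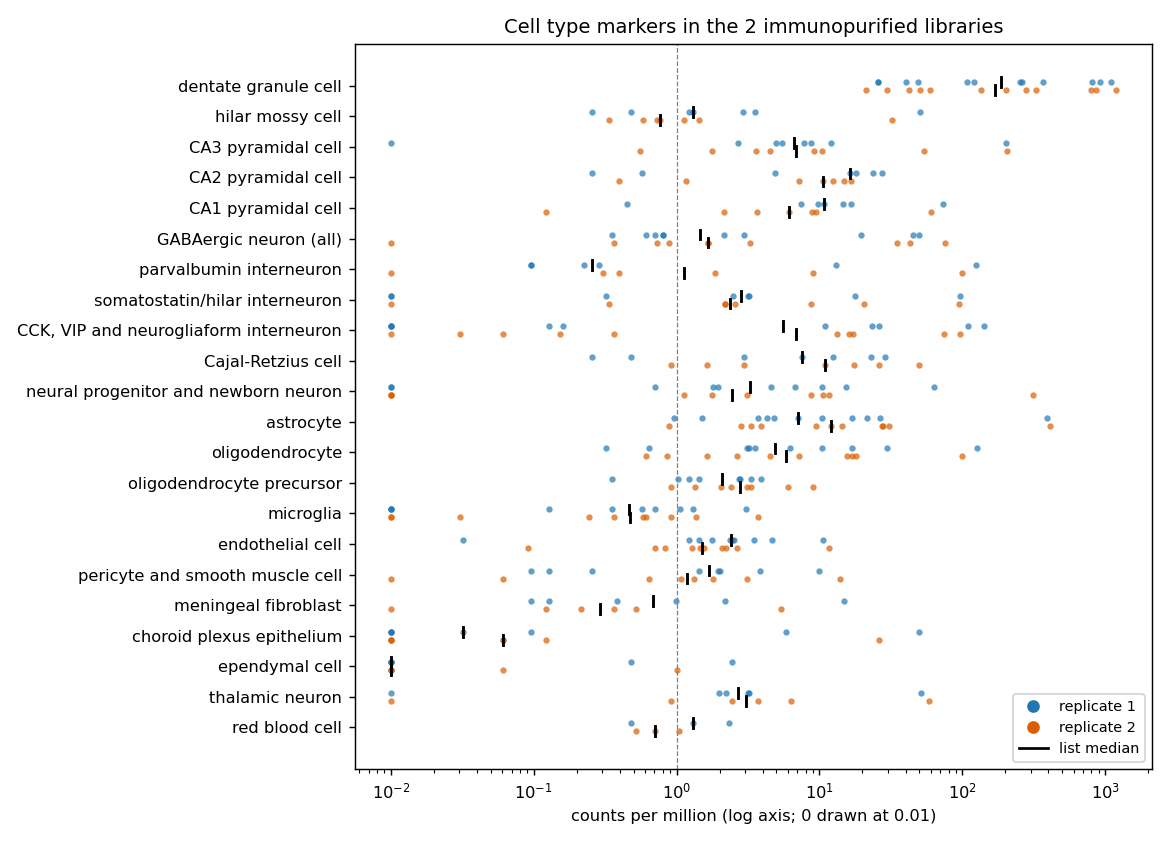
Normalised counts (CPM, log axis, 0 drawn at 0.01) of each cell type marker in replicate 1 (blue) and replicate 2 (orange), with list medians as black bars and a dashed line at 1 CPM. The 12 granule cell markers lie at a median of 180 CPM, while the medians of mossy cell and microglial markers are 1.04 and 0.584 CPM.

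Slc17a7, the vesicular glutamate transporter, was the highest of 16 transmitter identity genes at 339 ± 138 CPM. Gad1 and Gad2 came next, with the counts of Slc17a7 8.74 times those of Gad1 in replicate 1 and 3.19 times in replicate 2. Slc17a6 was at 3.46 ± 0.335 CPM, and Th, Slc6a4, Chat and Slc18a3, which mark catecholamine, serotonin and acetylcholine neurons, had 0 counts in both libraries.

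Among ionotropic glutamate receptors, Gria2 (1293 ± 186 CPM), Gria1 (654 ± 40.5 CPM) and Gria3 (392 ± 16.3 CPM) led the AMPA type and Gria4 was at 12.6 ± 3.68 CPM. Grik2 (77.2 ± 0.712 CPM) led the kainate type. NMDA receptor genes were Grin2b (267 ± 5.50 CPM), the obligatory subunit Grin1 (123 ± 27.1 CPM) and Grin2a (78.6 ± 4.27 CPM), and Grin2c (7.27 ± 4.46 CPM) and Grin2d (1.31 ± 0.0848 CPM) were lower. The metabotropic genes Grm5 (185 ± 28.0 CPM) and Grm2 (90.6 ± 18.1 CPM) stood above Grm7 (33.4 ± 6.40 CPM). GABA-A receptor genes included Gabra5 (315 ± 61.0 CPM) and Gabrb2 (286 ± 41.9 CPM). Gabrd, one of the subunits linked to tonic inhibition, was at 13.6 ± 0.509 CPM and Gabra6 had 0 counts.

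Each modulatory receptor family was carried by a few members. Of 14 serotonin receptor genes, 5 were detected, led by Htr1a (44.5 ± 9.04 CPM), Htr4 (20.3 ± 8.36 CPM) and Htr5a (17.6 ± 2.24 CPM). Drd5 (31.8 ± 8.98 CPM) and Drd1 (18.1 ± 13.7 CPM), both coupled to cAMP production, were the 2 dopamine receptor genes detected, and Drd3 had 0 counts. Adra1d (28.7 ± 2.94 CPM) led the adrenergic and Chrm1 (199 ± 28.7 CPM) the acetylcholine receptor genes. Of the 18 voltage-gated potassium channel genes, 17 were detected, among them Kcna1 (339 ± 66.0 CPM). The neuropeptide list also held granin genes and the neurotrophin gene Bdnf. Its highest members were Chgb (695 ± 276 CPM), Scg2 (262 ± 71.2 CPM), Bdnf (122 ± 86.4 CPM) and Cck. The opioid precursors Penk (33.6 ± 10.5 CPM) and Pdyn (26.9 ± 1.18 CPM) were similar in level.

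Housekeeping groups were well represented. Of 83 ribosomal protein genes 79 were detected, with Rpl4 the highest (782 ± 113 CPM), and all 75 nuclear-encoded subunits of oxidative phosphorylation were detected, led by Atp5b (1489 ± 109 CPM). Nuclear-retained long noncoding RNAs were not excluded from the purified RNA. Meg3 was at 2133 ± 51.7 CPM, Snhg11 at 306 ± 83.0 CPM and Miat at 275 ± 47.3 CPM.

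The 2 libraries ranked genes alike, but differed beyond counting error. Across the 19219 symbols with a count, which are not independent replicates, Pearson's r was 0.984 and Spearman's rho 0.966. The chi-square statistic of the counts was 67.8 times its degrees of freedom, so the libraries are not 1 library deposited under both names. The coefficient of variation from edgeR was 25.2%, with 21.1% for genes at a mean CPM of 100 or more and 32.9% for detected genes under 10 CPM. Of 8442 genes with a mean CPM of at least 10, 83.4% differed by less than 1.5-fold, 184 were at least 2-fold higher in replicate 2 and 85 at least 2-fold higher in replicate 1. Together these were 3.19% of genes. In the simulated libraries 5.52% of unchanged genes passed 2-fold, but every gene there had the common coefficient of variation. That value was estimated from these same 2 libraries, so it contains their differences, and it exceeds the DESeq2 gene-wise median of 14.3%. The 2 shares therefore cannot tell how many of these genes differ beyond noise. With library totals alone the counts were 130 and 129, since that scaling moved the median log2 ratio to -0.10 from -0.01.

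Genes switched on by neuronal activity stood higher in replicate 2. Of 16 immediate early genes with a mean CPM of at least 1, 11 were higher in replicate 2, 6 of them at least 2-fold, and none was 2-fold lower. Their median log2 ratio was 0.70, at percentile 100 of expression-matched lists. Egr3, a transcription factor gene on chromosome 14 (70077203 to 70082614, plus strand), was at 304 CPM in replicate 1 and 2071 CPM in replicate 2, a log2 ratio of 2.86 (95% counting interval 2.83 to 2.89). Arc, which controls AMPA receptor trafficking, was at 33.2 and 265 CPM (log2 ratio 3.08). Homer1, a postsynaptic gene whose transcript forms are counted together, was at 151 and 767 CPM (2.43). Fosl2 was at 90.3 and 233 CPM (1.46) and Fosb at 14.9 and 56.0 CPM. Other members did not share this. Egr1 had a log2 ratio of -0.29, Npas4 of -0.92 and Dusp1 of -0.75. Fos, at 2.47 ± 0.785 CPM, had a log2 ratio of 0.73 (0.27 to 1.24). Granule cell markers as a list did not differ, with a median log2 ratio of 0.10 (percentile 62.6).

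**Figure D2:**
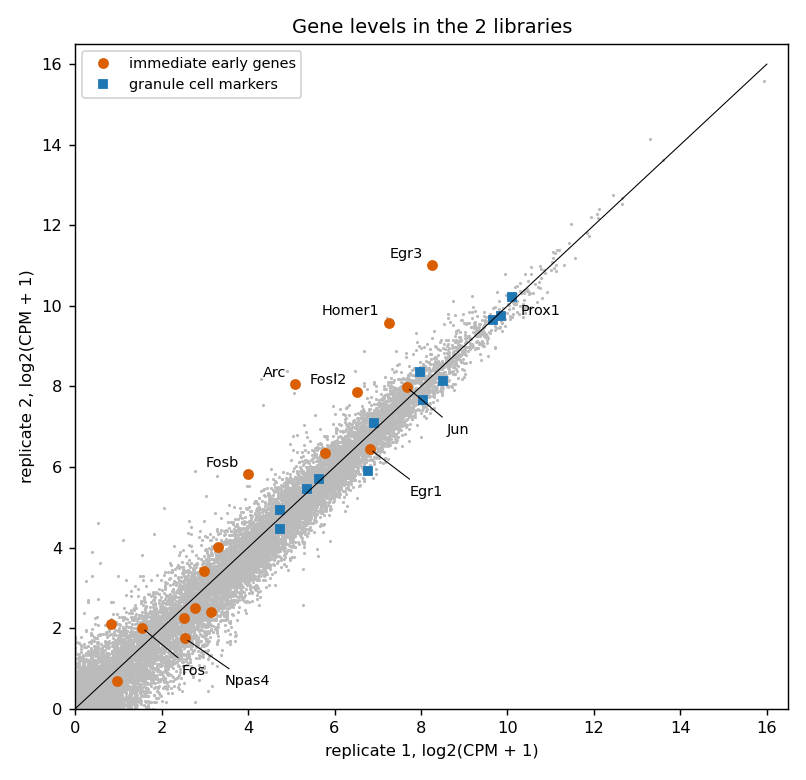
Level of each gene, as log2(CPM + 1), in replicate 1 (horizontal) and replicate 2 (vertical), with immediate early genes in orange, granule cell markers in blue and the line of equality. Egr3, Homer1, Arc, Fosl2 and Fosb lie above the cloud of genes (log2 ratios 1.46 to 3.08), whereas Egr1 and Npas4 lie below the line.

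The 10 genes with the largest ratio towards replicate 2 also included Baz1a, a chromatin remodelling subunit (0.447 and 23.6 CPM), Inhba, which encodes the activin subunit beta A (28.8 and 332 CPM, log2 ratio 3.62), the chaperone regulator Bag3 (3.13 and 30.6 CPM), the centromeric histone gene Cenpa (5.84 and 58.6 CPM), Samd4 (19.4 and 185 CPM), Fam129b (2.56 and 19.1 CPM) and Ier5 (32.5 and 226 CPM). The remaining one is listed under a cDNA clone identifier. Towards replicate 1 the ratios were smaller. Lypd6, a relative of Lypd1, was at 37.3 CPM in replicate 1 and 4.98 CPM in replicate 2 (log2 ratio -2.80), and Fgf10, Stk32b, Zfp385a, Timp2, Tox3, Fbxl7, Eefsec, Cpne8 and Epb4.1l4a had log2 ratios of -1.47 to -1.80. Lypd1 itself was lower in replicate 2 by a log2 ratio of -0.35.

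Of 38 lists compared between the libraries, 13 fell outside the central 95% of matched random lists, 8 above and 5 below. Independent genes and lists would give 1.9. Members of a list can vary together and some genes are in more than 1 list, so the excess cannot be read as a test. The neuropeptide list, which holds granin genes and Bdnf, was higher in replicate 2 (median log2 ratio 0.78, percentile 100). The neurotrophin gene Bdnf was at 1.67, Chgb at 0.93, Penk at 0.74 and Npy at 4.62, the last from 10 and 287 counts. Cck was lower at -0.85. With every counted gene that median was 0.40, at percentile 97.4, inside the range. The 2 dopamine receptor genes were higher, Drd1 with a log2 ratio of 1.81 and Drd5 with 0.67, but with every counted gene the list was at percentile 96.1. Cytosolic ribosomal protein genes had a median of 0.21 (percentile 99.7), with 59 of 79 above 0. Subunits of oxidative phosphorylation (-0.15, percentile 0), voltage-gated potassium channels (-0.27, percentile 0.49) and synaptic vesicle genes (-0.17, percentile 0.49) were lower in replicate 2, and the last of these lay at percentile 14.2 once a fit on exon length and GC content was removed. That fit moved the oxidative phosphorylation median to -0.06 (percentile 1.68) and the ribosomal protein median to 0.29, and library totals alone moved them to -0.24 and 0.12.

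Markers of other cells differed as well. All 6 CA1 markers compared were lower in replicate 2 (median -0.77, percentile 0.21), with Wfs1 (-0.20), Mpped1 (-0.81) and Fibcd1 (-0.54), and all 5 Cajal-Retzius markers were higher (0.59, percentile 98.8). Oligodendrocyte precursor (1.05, percentile 99.95, with 5 of 8 above 0) and astrocyte markers (0.39, percentile 99.0, with 7 of 10 above 0) had higher medians. Pdgfra was at 2.75 and 8.99 CPM and Slc1a2, with a small ratio, at 389 and 413 CPM. The astrocyte list was at percentile 97.2 with every counted gene. For GABAergic markers the median was 0.69 (percentile 99.3), with Gad1 and Gad2 higher (0.69 and 1.21) and Erbb4 and Lhx6 lower. That list lay at percentile 83.8 among genes with at least 20 counts in both libraries. The choroid plexus value rests on Kl (-0.85) and Ttr, with 182 and 4 counts, and was at percentile 7.53 with every counted gene. Mossy cell (-0.91, percentile 3.59), CA2 (-0.53, percentile 3.78, with 1 of 5 above 0) and CA3 markers (-0.10, percentile 40.5) lay within the range of random lists, though with at least 20 counts in both libraries the mossy cell list was at percentile 1.55.

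**Figure D3:**
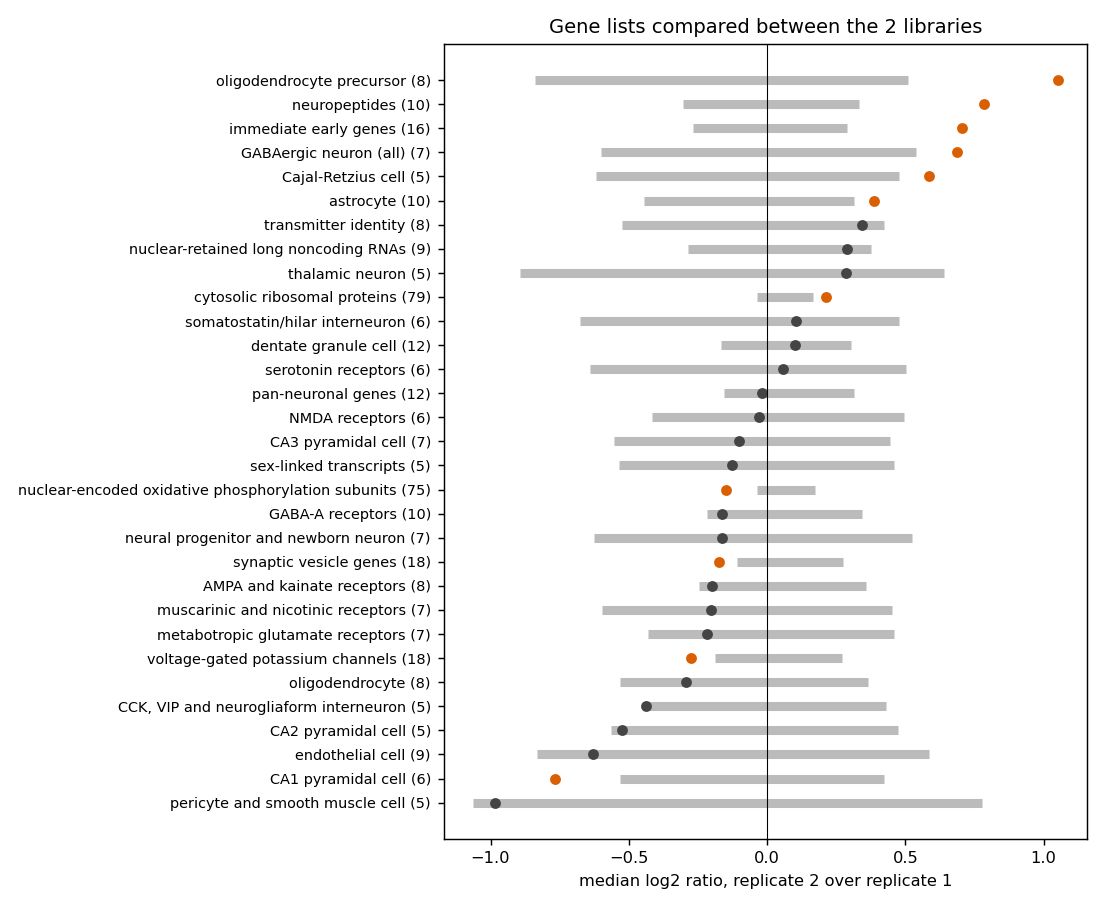
Median log2 ratio of replicate 2 over replicate 1 for each gene list with at least 5 members compared (number in brackets), with grey bars for the central 95% of matched random lists and orange points for medians outside it. Immediate early genes (0.70) and neuropeptides (0.78) lie far to the right of their bars, and CA1 markers (-0.77) to the left.

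The sex-linked transcripts were counted as a check of the libraries. The Y-linked genes were found in both, with Kdm5d at 34.7 CPM in replicate 1 and 25.4 CPM in replicate 2, Ddx3y at 25.6 ± 1.37 CPM, Eif2s3y at 18.5 ± 1.98 CPM and Uty at 17.8 ± 7.95 CPM. Xist, which is transcribed from the inactive X chromosome, had 15 counts in replicate 1 and 369 in replicate 2, which is 0.479 and 11.3 CPM, so the libraries differed in this transcript while both held Y-linked ones.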

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

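Counts outside the gene lines, which no comparison used, were the only signal singled out for a second look, since groups of 2 libraries allow no check for outlying samples. Reads that overlapped no annotated feature made up 16.7% of all lines in replicate 1 and 17.0% in replicate 2. Reads with more than 1 alignment made up 15.7% and 15.5%. Reads that overlapped several genes made up 2.61% and 2.56%. The 2 libraries have near-equal shares in all 3 classes.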

How the results depend on the processing

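The length and GC fit, the minimum of 20 counts, the totals without Rn45s and Lars2, and library totals alone for the counts of genes were chosen after the data were seen. Over all results, 425 values under another setting counted as the same and 104 did not. The delayed, rapid and clock lists were not run under another setting and are not among these values. The allowance was the SD between the libraries for level percentiles and the SD of random lists for list differences. For counts it was 1.5 times, and for the correlation an interval around it. Single-library percentiles were judged by a spread taken from those same values, and another scaling shifts every ratio by 1 amount. Such labels therefore say little. None of the 13 list medians outside the range of random lists changed sign. The immediate early gene median stayed between 0.61 and 0.79, at percentile 100, and that of CA1 markers between -0.86 and -0.54. Genes detected numbered 9576 to 14066. Genes at least 2-fold higher in replicate 1 numbered 129 with library totals alone, which shift every ratio by 1 amount. The GABAergic difference was 0.20 with at least 20 counts, which removes Dlx1, 0.20 with every counted gene, which adds members with few counts, and 0.17 after the length and GC fit, where the cause was not tested. With every counted gene, the astrocyte (97.2), dopamine receptor (96.1), neuropeptide (97.4) and choroid plexus (7.53) percentiles came inside the central 95%, as did those of GABAergic markers with every counted gene (81.3) and after the length and GC fit (77.9), and of synaptic vesicle genes (14.2) after that fit. Lists that moved outside it were mossy cell markers (1.55) with at least 20 counts, meningeal fibroblast markers (1.56) and AMPA and kainate receptors (1.07) with every counted gene, and CCK, VIP and neurogliaform interneuron markers (1.10) and GABA-A receptors (1.35) after the length and GC fit. The fibroblast list, at percentile 2.60 at first, was also outside with 10 bins and after the fit (2.38). Pearson's r was 0.967 with a pseudocount of 0.1 and 0.974 over detected genes. The coefficient of variation was 14.3% from DESeq2, as a median of gene-wise values. Level percentiles against detected genes alone were 0 for mossy cell, 0 for GABAergic, 9.07 for astrocyte and 2.24 for oligodendrocyte markers, a background without low genes. Per kilobase of exon they were 99.95 for granule cell and 0.99 for GABAergic markers, and as means of log2(CPM + 1) 1.77 for mossy cell and 6.21 for GABAergic markers; the cause was not tested. For oligodendrocyte markers single libraries gave 20.6 (replicate 1) to 29.6 (replicate 2). The setting without mitochondrially encoded genes was not run, as no symbol begins with mt-. Percentiles of list differences cannot move with the scaling. Ratios of genes near 1 CPM are less certain. The SD of log2 ratios was 0.959 for means of 1 to 10 CPM, against 0.465 for means of 10 to 100 CPM. How much of that spread is due to depth was not tested.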

Other observations

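The tests of nuclear RNA, of CA field tissue and of the length and GC trend were chosen after the results were seen, and the bounds of these 3 tests were rewritten after a first run had given their values. The nuclear RNA test was rewritten again, to take in Malat1 and Xist, then to leave out Xist as sex-linked, and last to ask that its bound also hold with every counted gene, with all their values known. The lists of delayed and rapid activity genes were chosen after the immediate early genes had been seen, and the clock list after those 2 lists, each before its members' own values were looked at, though delayed and rapid genes were known not to be among the most different genes. Genes named here from these lists were chosen after their values were seen.

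Further genes known to follow neuronal activity also stood higher in replicate 2. Of 15 delayed activity genes, 12 were higher and 5 at least 2-fold, with a median log2 ratio of 0.75. Nrn1, which encodes a surface protein that promotes neurite growth, was at 391 CPM in replicate 1 and 894 CPM in replicate 2, the GTPase gene Rheb at 160 and 346 CPM, the phosphatase gene Dusp4 at 23.2 and 46.6 CPM and the prohormone convertase gene Pcsk1 at 0.990 and 8.83 CPM. Of 8 rapid activity genes with a mean CPM of at least 1, 6 were higher and 4 at least 2-fold. Atf3 was at 0.319 and 13.8 CPM and Gadd45b at 4.31 and 13.2 CPM, while Klf2 (log2 ratio -1.16) and Ier3 (-1.11) were lower.

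For the activity genes higher in replicate 2, the 7 clock output genes had a median log2 ratio of -0.15, with 1 of 7 above 0. By the bound written beforehand, this counted against a large difference in time of day. Bhlhe41, a clock repressor gene outside that list, went the other way, at 101 and 474 CPM (log2 ratio 2.32). A difference in time of day is therefore not excluded. More nuclear RNA in replicate 2 stays open. The 8 nuclear-retained RNAs that are not sex-linked had a median of 0.29, at percentile 92.9, inside the range of random lists. They were uneven, with Malat1 at a log2 ratio of 0.92 and Snhg11 at -0.47. With their SD of 0.397 the median comes to 0.68. That is under the 0.70 of the immediate early genes but over their 0.67 with every counted gene. The forms of this test without Malat1 and Xist, and the form without Xist at 0.70 alone, had counted against it, while with Xist the SD was 1.44 and nothing was decided. A response to neuronal activity in the cells of replicate 2 is also open as a hypothesis. The delayed list lay at percentile 100 and the rapid list at 99.87, but neither was run under another setting. The rapid value rests on 8 of 11 members, and Atf3 reached a mean CPM of 1 through replicate 2 alone. The source of such a response was not tested, and the lower Egr1, Npas4 and Dusp1 do not follow it. Whether the libraries differ in the sex of pooled animals was not tested: Xist had 15 and 369 counts, but the Y-linked genes were present in both, with log2 ratios of 0.20 for Ddx3y, -0.13 for Eif2s3y, -0.35 for Kdm5d and -0.85 for Uty. The design names no difference between the libraries, and handling, housing or pooling of animals is not described in the labels.

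For the CA1 markers lower in replicate 2 (median log2 ratio -0.77), no test decided. More CA field tissue in replicate 1 may be a source, but the 12 CA2 and CA3 markers pooled had a median of -0.27, of the same sign and at percentile 10.7, inside the range of random lists (CA2 -0.53, CA3 -0.10). A gene length or GC trend moved the CA1 median to -0.54 (percentile 1.44 of random lists, whose SD was 0.236), which leaves the trend open as a part of the difference. Under the bounds as first written, which took no account of spread, both values would have counted against these explanations; they were rewritten to ask for a distance beyond the SD of random lists, and neither value then decided.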
